A study of Homo sapiens with 10 samples.

How the data were processed

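Polyadenylated RNA of 2 prostate cancer cell lines was sequenced in 10 libraries: 22Rv1 control and CITED2 with 2 libraries each, and LNCaP control and CITED2 with 3 libraries each. Per the labels' protocols, total RNA was isolated with a magnetic bead kit, messenger RNA was enriched by its poly-A tail, libraries were built with TruSeq chemistry, and sequencing was done on an Element AVITI instrument. The submitters' processing notes name kallisto 0.44.0, DESeq2 and the genome build GRCh38.p12, without saying which step each was used for. The authors deposited a single table of estimated counts with 36459 gene symbols and 10 columns; its values are whole numbers that differ in total between libraries, and rounding to whole numbers before testing changed none of them. How transcripts were summed to genes, and whether strand was used, is not given in the sources used here, so overlapping and antisense genes cannot be told apart with certainty, and estimated counts divide reads among near-identical copies by a model. Each column was matched to its library through the sample number in the labels, and no other column of sample values was present.

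The total per library ran from 14910457 to 23790379 counts. The replicates of a group differed by more than sampling noise in all 8 pairs (chi-square per degree of freedom 91.2 and 105 for the pairs with LNCaP CITED2 replicate 2, and 2.75 to 5.94 for the others), so no library was counted as a repeat of another. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

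Tests were run in R 4.3.3. Genes were kept by edgeR's filterByExpr over the 4 groups, which left 16087, and libraries were scaled by TMM. The main test was the quasi-likelihood F test of edgeR 4.0.16 on one model with a mean for each of the 4 groups and all 10 libraries, leaving 6 residual degrees of freedom. Its contrasts were CITED2 minus control in 22Rv1, the same in LNCaP, and the LNCaP effect minus the 22Rv1 effect. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the tested genes, with a threshold of 0.05; standard errors were taken from the log2 fold change and its F value. CPM values use TMM-scaled library sizes and are given as mean ± SD.

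Before the data were examined, 23 gene lists were fixed: HIF targets, androgen-responsive genes, mesenchymal and matrix genes, epithelial genes, neuroendocrine genes, bone and bone metastasis genes, cell cycle genes, nucleolar and MYC target genes, interferon-stimulated genes, NF-kB targets, TGF-beta and BMP response genes, cholesterol synthesis genes, unfolded protein and amino acid response genes, oxidative phosphorylation genes, p53 targets, immediate early genes, WNT targets, the CITED family and its partners, genes near CITED2, and markers of fibroblasts, immune cells, endothelium and basal epithelium. Of the listed genes, TGFB1 was not analysed here. Lists with at least 5 tested members, 21 in all, were compared with other genes by camera in limma 3.58.1 on log2 CPM with a preset correlation of 0.01, and adjusted over the lists. With an estimated correlation the cell cycle call in LNCaP and in the difference between lines held, and no other call did.

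The rule for named genes was also fixed beforehand: CITED2 first, then in each line the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 5 CPM in the higher group, the 10 genes called alike in both lines with the smallest larger p, the 6 genes with the smallest p for the difference between lines, and for each list and line up to 4 called members with the smallest p, or up to 2 as values where none was called. For 22Rv1 the rule was also applied to the fit of its 4 libraries alone, a choice made after the counts of calls were seen. MKI67, MCM4, PCNA, KLK2 and TMPRSS2 in LNCaP are members of fixed lists named beyond that rule, after their values were seen. The same holds for PDIA4, CALR, DNAJC3, HYOU1 and HERPUD1 in LNCaP. CACNA1H, under 5 CPM, and SOX11 in LNCaP were also named after their values were seen, as were the genes in the additional observations. Some genes that the rule selects are not reported here. Gene positions come from GENCODE 29 on GRCh38, in which 35377 of the symbols were found.

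The alternatives fixed beforehand were DESeq2 size factors in edgeR, library totals only, the DESeq2 1.42.0 Wald test, limma voom, no filter and a stricter filter (1 CPM in at least 2 libraries), each cell line alone, the replicate number as a block, each library left out in turn, an adjusted p under 0.01, a fold of at least 2, and for lists fry and an estimated correlation. Voom with a quality weight per library and a correction of each library's trend on GC content and length (available for 98.7% of tested genes) were added after the data were seen. The tests were tried on simulated counts over 15798 genes, with the control means of each line, the real depths and the spread per gene estimated from all 10 libraries. In the 22Rv1 comparison 36 of 100 genes changed 2-fold and 93 of 100 changed 4-fold were recovered, with 4 false calls among 133. In the LNCaP comparison 66 and 94 of 100 were recovered, with 17 false calls among 204. There the 31 cell cycle genes were also lowered 2-fold, and their calls are among the 204. The simulation had no library that stood apart, but its spread per gene included that of LNCaP CITED2 replicate 2.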

Results

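The study raised CITED2, a transcriptional co-regulator without DNA-binding activity of its own that binds the p300 and CBP coactivators, in 2 human prostate cancer cell lines and measured polyadenylated RNA. Per the series' design note, CITED2 came from a CRISPR activation screen for drivers of metastasis. The comparison asks which transcripts moved when it was raised. In 22Rv1, a line grown from a prostate carcinoma xenograft, CITED2 was raised by CRISPR activation, in which a guide RNA brings an activator to the gene's own promoter. The labels name 1 clone carrying either a control guide or a CITED2 guide, with 2 libraries each. In LNCaP, an androgen-sensitive line from a lymph node metastasis, CITED2 was raised from a cDNA and compared with control cells, with 3 libraries each. The 10 libraries held between 14910457 and 23790379 estimated counts over 36459 gene symbols. The line and the way of raising CITED2 changed together, so a difference between the lines cannot be assigned to either.

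CITED2 RNA was higher in every library in which it was meant to be raised. In 22Rv1 it went from 47.1 ± 4.05 CPM (counts scaled to a common library total, mean ± SD, n = 2) to 572 ± 20.9 (n = 2), or 12.1-fold. The log2 fold change was 3.60 with a standard error (SE) of 0.21 (edgeR quasi-likelihood test, adjusted p = 9.08e-05). In LNCaP, whose control level was already higher, it went from 335 ± 23.8 CPM (n = 3) to 1808 ± 422 (n = 3), or 5.39-fold. The log2 fold change was 2.43 (SE 0.165, adjusted p = 7.77e-06). The LNCaP effect minus the 22Rv1 effect was -1.17 (SE 0.25, adjusted p = 0.0373). CITED2 lies on chromosome 6 from 139371807 to 139374620 on the minus strand in GRCh38. Its count in LNCaP can include transcripts of the introduced cDNA as well as of the resident gene. Of 10 listed genes near CITED2 on the same chromosome arm, 7 were measured, and in 22Rv1 none was called. In LNCaP VTA1, which works in endosomal sorting, fell by 1.30 on the log2 scale (SE 0.11, adjusted p = 5.74e-05) and ABRACL fell by 0.78 (SE 0.17, adjusted p = 0.0221).

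**Figure D1:**
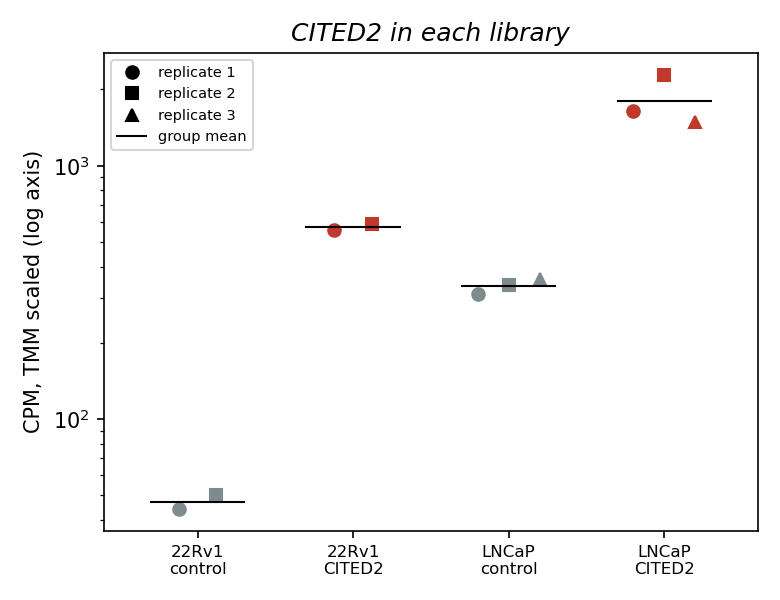
CITED2 in each of the 10 libraries, as TMM-scaled CPM on a log axis; each point is a library, its shape the replicate number, and the line is the group mean. The 22Rv1 means are 47.1 and 572 CPM, the LNCaP means 335 and 1808 CPM, and the control and CITED2 libraries do not overlap in either line.

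In LNCaP, raising CITED2 went with a steep fall of the genes of cell division. All 31 members of the cell cycle list fell, with a median log2 fold change of -2.90. The list was called lower than other genes (camera, adjusted p = 4.6e-44, and adjusted p = 7.48e-05 with an estimated correlation). TOP2A, the topoisomerase of dividing cells, went from 82.9 ± 1.35 to 1.71 ± 0.625 CPM (n = 3 each), a log2 fold change of -5.57 (SE 0.21, adjusted p = 2.17e-07). MKI67, which encodes the proliferation marker Ki-67, went from 93.5 ± 11 to 8.82 ± 2.74 CPM (log2 fold change -3.40, SE 0.21, adjusted p = 4.33e-06). CDC20 and BIRC5, which act in mitosis, had log2 fold changes of -4.63 (SE 0.148) and -4.93 (SE 0.187), and the spindle protein gene TPX2 of -2.90 (SE 0.105). Among members that act in DNA replication, RRM2, a ribonucleotide reductase subunit gene, had a log2 fold change of -4.21 (SE 0.132). The helicase subunit gene MCM4 had -1.74 (SE 0.097) and the sliding clamp gene PCNA -0.68 (SE 0.128). The list was also split after the fall was seen. The 11 members grouped as S phase had a median of -1.16. The 20 others, grouped as mitotic, had a median of -3.69. They are all the remaining members, among them MKI67, TOP2A and the regulator FOXM1, and not only genes of mitosis.

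Among the 10 lowest log2 fold changes in LNCaP, TOP2A and UBE2C belong to the fixed cell cycle list. NUSAP1, a spindle protein gene, went from 35.5 ± 1.88 to 0.585 ± 0.137 CPM (log2 fold change -5.90, SE 0.16, adjusted p = 1.03e-07), and IQGAP3, HMMR, NCAPG, UBE2C, CKAP2L and DLGAP5 had log2 fold changes of -5.70, -5.62, -5.56, -5.48, -5.22 and -5.21. MND1, a recombination gene, went from 280 counts over the 3 control libraries to 3 counts over the 3 CITED2 libraries, a ratio of 85.4 (95% interval from the counts alone 28.9 to 417). At the other end, besides CITED2, CD55, a complement inhibitor, rose from 2.36 ± 0.583 to 13.9 ± 1.56 CPM (log2 fold change 2.55, SE 0.18, adjusted p = 1.08e-05), and the pro-apoptotic gene HRK from 1.02 ± 0.40 to 5.95 ± 1.63 CPM (log2 fold change 2.54, SE 0.31). ARG2, the mitochondrial arginase, reached 658 ± 177 CPM from 169 ± 10.2 (log2 fold change 1.96, SE 0.19, adjusted p = 0.000111), and CD274, which encodes the immune checkpoint ligand PD-L1, reached 152 ± 10.8 CPM from 43.3 ± 2.95 (log2 fold change 1.81, SE 0.13, adjusted p = 1.26e-05). SERPINA3, ARHGAP9, LAT2, RLN2, IGHG4 and NDUFA4L2 completed the 10 highest, with log2 fold changes of 2.07, 1.98, 1.81, 1.78, 1.77 and 1.69. IGHG4 can share reads with the other immunoglobulin heavy constant genes, so its value is uncertain.

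Genes of the unfolded protein and amino acid responses rose in LNCaP: with all libraries 11 of 21 members rose and none fell, with a median log2 fold change of 0.81, and 15 rose when p-values were adjusted over the list alone. Examples were PSAT1 of serine synthesis, from 411 ± 14.8 to 987 ± 111 CPM (log2 fold change 1.27, SE 0.11, adjusted p = 4.61e-05), the stress transcription factor DDIT3 (1.29, SE 0.13, adjusted p = 0.000172), the asparagine synthetase gene ASNS (1.13, SE 0.13, adjusted p = 0.000323) and the mitochondrial folate enzyme gene MTHFD2 (0.81, SE 0.10, adjusted p = 0.000896). The rise was uneven within the list. PDIA4, CALR and DNAJC3 had log2 fold changes of 0.14, 0.04 and 0, and HYOU1 and HERPUD1 of 0.82 and 1.03. The list was called higher by camera at adjusted p = 2.89e-10, and the call was lost at adjusted p = 0.225 with an estimated correlation. Without LNCaP CITED2 replicate 2 the median was 0.52, 16 members rose and 1 fell, and the list was called at adjusted p = 2.8e-09 (adjusted p = 0.102 with an estimated correlation). The basal epithelium list was also called higher (adjusted p = 0.0298, and adjusted p = 0.225 with an estimated correlation), with 1 of its 6 measured members called: the keratin gene KRT17 rose from 0.18 ± 0.00615 to 1.55 ± 0.372 CPM (log2 fold change 3.06, SE 0.57, adjusted p = 0.00958). KRT17 was near the floor of 3 counts per library in the LNCaP controls and can share reads with related keratins, so its value is uncertain. It missed the threshold without LNCaP control replicate 1, 2 or 3 (adjusted p = 0.0548, 0.0542 and 0.05), and the list was not called without LNCaP CITED2 replicate 2 (adjusted p = 0.163), where 2 members rose.

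Androgen-responsive genes moved both ways in LNCaP: 8 of 25 rose and 3 fell (9 and 6 adjusted over the list alone). KLK3, which encodes prostate-specific antigen, fell from 369 ± 28.1 to 27.4 ± 5.05 CPM (log2 fold change -3.76, SE 0.16, adjusted p = 2.88e-07), a 13.5-fold drop. KLK2, a related kallikrein gene, fell by 0.63 (SE 0.12, adjusted p = 0.0111). In contrast SLC45A3, also known as prostein, rose from 137 ± 3.41 to 365 ± 99.4 CPM (log2 fold change 1.41, SE 0.17, adjusted p = 0.00052), and CENPN and PMEPA1 rose by 1.30 (SE 0.112) and 1.10 (SE 0.122). The transmembrane protease gene TMPRSS2 rose by 0.53 (SE 0.119). The list as a whole was not called (adjusted p = 0.671), with a median of 0.07 and a mean of -0.10. Without LNCaP CITED2 replicate 2, 12 rose and 6 fell, and the median was 0.22.

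**Figure D2:**
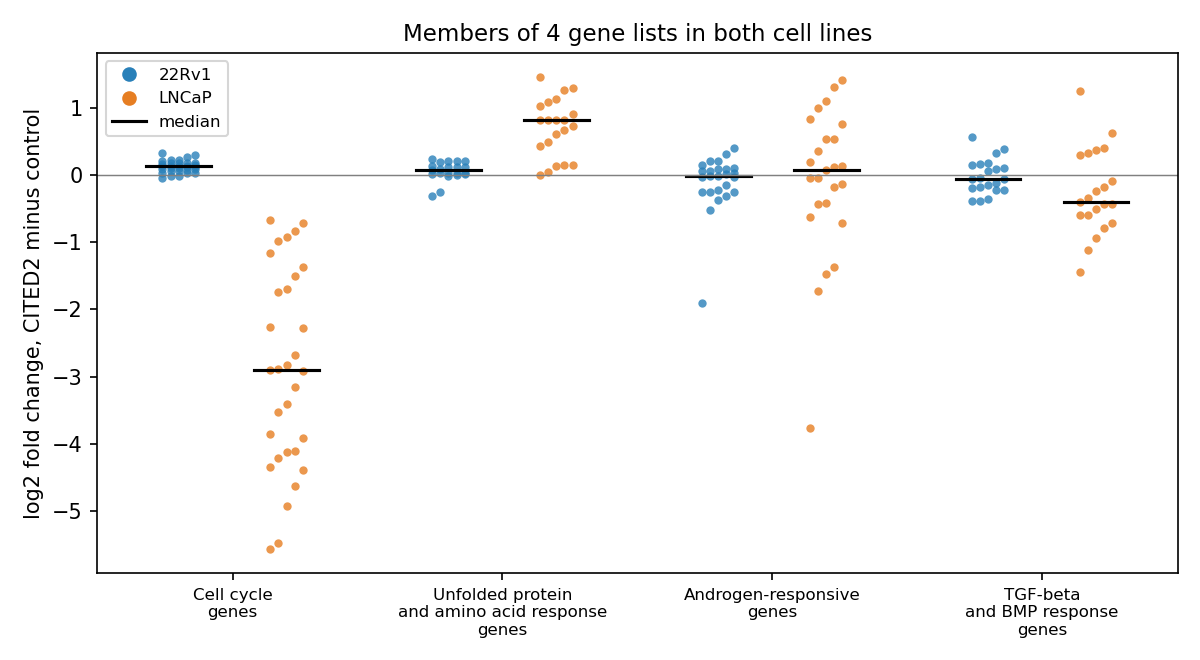
Log2 fold changes, CITED2 minus control, of the measured members of 4 gene lists in 22Rv1 and LNCaP; each point is a gene and the black line is the median of the list in that line. The cell cycle members spread below 0 in LNCaP around a median of -2.90 and lie close to 0 in 22Rv1, where their median is 0.13.

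Of the lists tied to metastasis and signalling, 5 of 21 TGF-beta and BMP response genes fell in LNCaP and none rose, among them ID3, ID2, BAMBI and LTBP3 with log2 fold changes of -1.44 (SE 0.276), -1.12 (SE 0.252), -0.79 (SE 0.18) and -0.51 (SE 0.114). Adjusted over the list alone, 1 rose and 7 fell. The list missed the threshold (adjusted p = 0.0702). In the mesenchymal and matrix list 3 of 22 fell and none rose: the collagen gene COL1A1 (-1.79, SE 0.192, adjusted p = 0.000236), the fibronectin gene FN1 (-1.17, SE 0.159) and the vimentin gene VIM (-1.02, SE 0.187). Adjusted over the list alone, 2 rose and 3 fell. Of the epithelial genes ESRP1 and GRHL2 rose by 0.59 and 0.36 and DSP fell by 0.73, and 16 of 19 were not called. Of 15 measured bone and bone metastasis genes 2 fell, ADAMTS1 (-0.59, SE 0.106) and BMP6 (-1.24, SE 0.327), and none rose. Of 24 HIF targets 3 rose, STC2 by 0.99 (SE 0.09), the glucose transporter gene SLC2A1 by 0.85 (SE 0.21) and the hexokinase gene HK2 by 0.54 (SE 0.11), and none fell, with the list at adjusted p = 0.0702. Without LNCaP CITED2 replicate 2, 8 HIF targets rose and 4 fell, and their median moved from 0.17 to 0.08. Without that library 9 TGF-beta and BMP response genes fell and none rose, and 5 bone genes fell and none rose. Of the mesenchymal and matrix genes 2 rose and 3 fell without it, and of the epithelial genes 4 rose and 2 fell, with the medians moving from 0.14 to -0.08 and from 0.17 to -0.01. The bone median moved from -0.12 to 0.01.

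Among NF-kB targets RELB and TNFAIP3 rose by 1.25 and 0.89 and TNFAIP2 fell by 0.88, of 14 measured. Among 23 interferon-stimulated genes OASL and IFIT3 rose by 0.94 and 0.70 and OAS3 fell by 1.35. The growth factor gene GDF15 rose by 0.89 and the repair gene DDB2 fell by 0.57 among 23 p53 targets. Of 17 immediate early genes ATF3, JUND and ZFP36 rose by 0.78, 0.75 and 0.51 and FOS fell by 1.02. The neuroendocrine gene SYT4 (-1.81), the WNT list gene TNFRSF19 (-0.83) and the fibroblast list gene COL6A1 (-0.59) were each the single call of their list. RRP12 rose by 0.67 as the single call among 27 nucleolar and MYC target genes. No member was called among 23 cholesterol synthesis genes, 29 oxidative phosphorylation genes or 15 CITED family members and partners, nor among the 4 immune and 2 endothelial markers measured, which were too few for a list test. Apart from the endothelial markers, still at 0 calls, these counts changed without LNCaP CITED2 replicate 2: 2 cholesterol synthesis genes rose and 5 fell, 8 oxidative phosphorylation genes fell, 1 CITED family member or partner rose and 2 fell, and 1 immune marker fell. Without it the numbers that rose and fell were 5 and 1 for NF-kB targets, 6 and 1 for interferon-stimulated genes, 3 and 2 for p53 targets, and 4 and 2 for immediate early genes. They were 1 and 2 for neuroendocrine genes, 1 and 1 for WNT targets, 0 and 2 for fibroblast markers, and 6 and 1 for nucleolar and MYC target genes. The oxidative phosphorylation list had a median of 0.13 with all libraries, and a median of -0.11 and a call for lower values without LNCaP CITED2 replicate 2 (adjusted p = 0.00421, and adjusted p = 0.434 with an estimated correlation). Median, mean and test differed in sign in 6 lists in LNCaP, none of them called: androgen-responsive genes, mesenchymal and matrix genes, bone genes, cholesterol synthesis, immediate early genes, and the CITED family and partners. In 22Rv1 they differed for mesenchymal and matrix, epithelial and fibroblast genes, also not called.

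**Figure D3:**
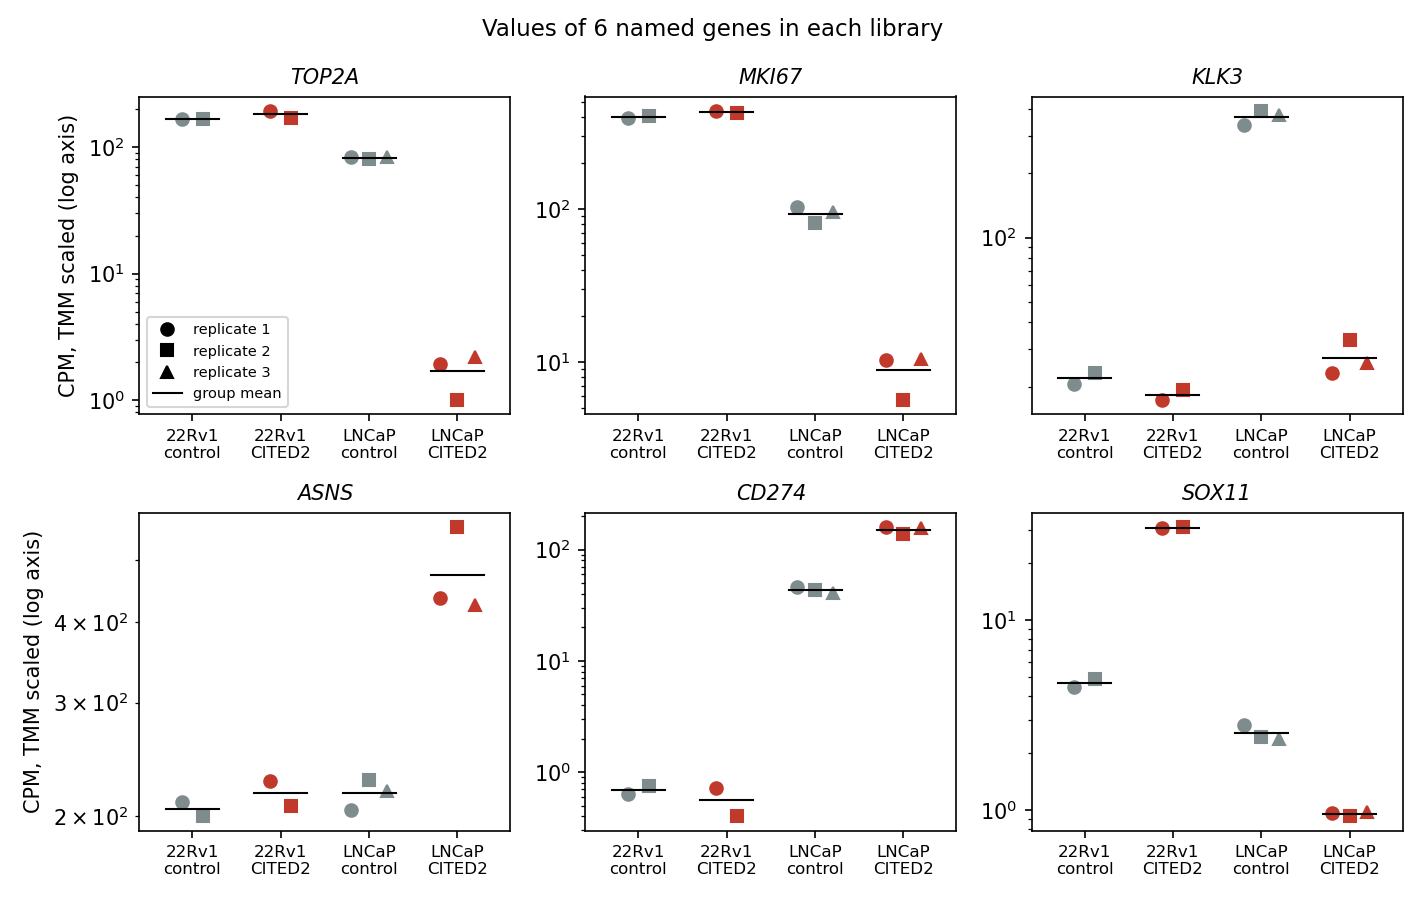
TMM-scaled CPM of TOP2A, MKI67, KLK3, ASNS, CD274 and SOX11 in each of the 10 libraries, on a log axis in each panel; shapes give the replicate number and lines the group mean. In LNCaP the mean of TOP2A goes from 82.9 to 1.71 CPM and that of KLK3 from 369 to 27.4, while SOX11 goes from 4.68 to 30.7 in 22Rv1 and from 2.54 to 0.96 in LNCaP.

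In all, 1164 of 16087 tested genes were called in LNCaP, 462 higher and 702 lower (edgeR quasi-likelihood test, adjusted p under 0.05), and 537 of them changed at least 2-fold. LNCaP CITED2 replicate 2 stood apart from the other libraries: mitochondrially encoded transcripts took 19.9% of its counts against 12.9 to 15.5% elsewhere, ribosomal protein genes took 11.3% against 6.0 to 8.6%, and its TMM factor was 0.79 against 0.97 to 1.06. Without it 4094 genes were called (1958 higher and 2136 lower), and these included all 1164, each with the same sign. Without LNCaP control replicate 1, 2 or 3 the counts were 611, 609 and 608.

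In 22Rv1 the response beyond CITED2 was small in size. SOX11, a neural and developmental transcription factor gene, rose from 4.68 ± 0.312 to 30.7 ± 0.176 CPM (n = 2 each), a log2 fold change of 2.71 (SE 0.16, adjusted p = 9.08e-05), and CACNA1H, a T-type calcium channel subunit gene, fell from 2.87 ± 0.114 to 0.57 ± 0.025 CPM, a log2 fold change of -2.31 (SE 0.24, adjusted p = 0.0135). With CITED2 these were the 3 genes called among 16087 by edgeR. At an unadjusted p under 0.05 there were 725. DESeq2 called 27, these 3 among them, and voom called 3, of which only 2 were among these 3. The calls rested on a spread estimated over all 10 libraries, LNCaP CITED2 replicate 2 included. Without that library 737 genes were called in 22Rv1 (281 higher and 456 lower). A fit of the 4 22Rv1 libraries by themselves called 487 (213 higher and 274 lower), of which 53 changed at least 2-fold. CACNA1H also passed in that fit (adjusted p = 0.00427). With the replicate number as a block in the joint fit, 2 genes were called, both higher, so CACNA1H was not called. In the joint fit it missed the threshold without 22Rv1 control replicate 1 or 2 (adjusted p = 0.0891 and 0.163), 22Rv1 CITED2 replicate 1 or 2 (0.263 and 0.337), or LNCaP control replicate 1, 2 or 3 (0.0561, 0.0576 and 0.0599).

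In the fit of the 22Rv1 libraries alone, the tubulin gene TUBA1A rose from 45.4 ± 1.60 to 90.0 ± 1.98 CPM (log2 fold change 1.00, SE 0.08, adjusted p = 1.53e-06) and SH3BGR from 31.9 ± 1.05 to 57.6 ± 0.56 CPM (0.86, SE 0.08, adjusted p = 4.37e-05). The signalling factor gene STAT6, the cancer-testis antigen gene MAGEC2, the protocadherin gene PCDHB11 and ARNT2, a partner of bHLH-PAS factors, rose by 1.23, 1.03, 0.90 and 0.85, and 3 loci with clone-based names, AC068946.2, AL139300.1 and AC067968.1, by 0.91, 0.84 and 0.84. Lowest were the phospholipase gene PLA2G3, from 10.9 ± 0.0218 to 3.01 ± 0.285 CPM (log2 fold change -1.85, SE 0.18, adjusted p = 3.32e-05), and the collagen gene COL6A2, from 5.87 ± 0.306 to 1.77 ± 0.294 CPM (-1.71, SE 0.24, adjusted p = 0.00124). PLEKHB1, DIO3, MUC19, DLX2, ALS2CL and FAXDC2 had log2 fold changes of -1.37, -1.34, -1.16, -1.11, -1.09 and -1.07, and CFAP221 went from 6.09 ± 0.679 to 3.04 ± 0.255 CPM (adjusted p = 0.0185). PCDHB11 can share reads with the other protocadherin beta genes, so its value is uncertain. None of these genes was called with all 10 libraries.

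Cholesterol synthesis genes were called lower as a list in 22Rv1 (median log2 fold change -0.17, adjusted p = 0.0104, and adjusted p = 0.295 with an estimated correlation), although none of its 23 members was called with all 10 libraries and 2 were when adjusted over the list alone. In the 22Rv1 libraries alone 5 of them fell, among them SREBF2, the regulator of the pathway (-0.37, SE 0.069, adjusted p = 0.00888), STARD4 (-0.37) and IDI1 (-0.32). The cell cycle list was called slightly higher (median 0.13, adjusted p = 0.011, and adjusted p = 0.203 with an estimated correlation), with no member called over all 10 libraries and PCNA up by 0.30 (SE 0.07, adjusted p = 0.0243) in the 22Rv1 libraries alone. The neuroendocrine list was not called, but 5 of its 13 members rose in the 22Rv1 libraries alone, including SYT4 by 0.70 (SE 0.09, adjusted p = 0.000492), SCG3 by 0.58 (SE 0.08), SCG2 by 0.81 (SE 0.18) and CHGB by 0.35 (SE 0.07). SCG2, SCG3 and CHGB are granin genes of secretory vesicles. The joint fit without LNCaP CITED2 replicate 2 called 7 cholesterol synthesis genes lower, 2 cell cycle genes higher and 5 neuroendocrine genes higher in 22Rv1. The remaining lists were not called in 22Rv1 with all 10 libraries, with adjusted p from 0.0538 to 0.719.

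The response differed between the lines in 419 genes when the difference itself was tested, 86 of them with the higher effect in LNCaP and 333 with the lower (edgeR quasi-likelihood test, adjusted p under 0.05). The genes with the smallest p were NUSAP1, NCAPG, RRM2, CDC20, EXO1 and KIF20A, of which RRM2 and CDC20 belong to the fixed cell cycle list, with differences, LNCaP effect minus 22Rv1 effect, of -6.18, -5.91, -4.38, -4.72, -4.60 and -5.28. All 31 cell cycle genes were in this set, with a median difference of -2.99. SOX11 rose in 22Rv1 and fell by 1.40 in LNCaP (SE 0.18, adjusted p = 0.00079), a difference of -4.11 (SE 0.23, adjusted p = 5.37e-06). Without LNCaP CITED2 replicate 2 the count was 2835, and all 419 were among them. It was 232 and 242 without 22Rv1 control replicate 1 and 2, 257 and 243 without 22Rv1 CITED2 replicate 1 and 2, and 273 and 278 without LNCaP control replicate 1 and 3. The lists called in the difference were the cell cycle (camera, adjusted p = 4.73e-51, and 4.81e-05 with an estimated correlation), the unfolded protein and amino acid response (7.82e-07, and 0.318 with an estimated correlation), HIF targets (0.0152 and 0.318) and basal epithelium (0.00681 and 0.259).

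CITED2 was the 1 gene called in the same direction in both lines. Across the other tested genes the fold changes of the 2 lines showed no correlation (Pearson r = -0.01, Spearman rho = -0.05, across genes, which are not independent replicates). Independent lists of these sizes would have shared 0.0574 genes called higher and 0.0436 called lower. With 3 genes called in 22Rv1 an overlap could hardly be seen. Without LNCaP CITED2 replicate 2, 56 genes rose in both lines against 34.2 for independent lists, and 108 fell in both against 60.6. Another 83 rose in 22Rv1 and fell in LNCaP against 37.4, and 61 did the opposite against 55.6. Both sets of calls come from 1 fit with a shared spread per gene, so the numbers for independent lists are not what no shared effect would give, and no test of the overlap is reported.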

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

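The tests of GC trend, of depth, of LNCaP CITED2 replicate 2 as the source of the cell cycle fall and of fewer cells in cycle were chosen after the results were seen. Of the named genes, 40 had different effects in LNCaP and 22Rv1 by a test of the difference itself (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). The named genes were chosen from these same data, 6 of them by this test, so their number and directions reflect that choice. The differences below are the LNCaP effect minus the 22Rv1 effect on the log2 scale, and 23 were negative and 17 positive. Line and method of raising CITED2 changed together, so these differences cannot be assigned to either.

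Negative differences were MND1 -6.44, NUSAP1 -6.18, HMMR -5.95, NCAPG -5.91, TOP2A -5.71, IQGAP3 -5.67, UBE2C -5.62, DLGAP5 -5.45, CKAP2L -5.45, KIF20A -5.28, BIRC5 -5.11, CDC20 -4.72, EXO1 -4.60, RRM2 -4.38, TPX2 -3.03 and PCNA -0.96. Further negative differences were SOX11 -4.11, KLK3 -3.50, SYT4 -2.50, COL1A1 -2.16, VTA1 -1.46, OAS3 -1.38 and CITED2 itself -1.17. Positive differences were TMPRSS2 0.91, PMEPA1 1.00, ASNS 1.04, PSAT1 1.07, DDIT3 1.08, CENPN 1.22, SLC45A3 1.35, COL6A2 1.38, LAT2 1.64, RLN2 1.77, NDUFA4L2 1.85, PLEKHB1 1.85, ARG2 1.93, CD274 2.10, CD55 2.28, CACNA1H 2.37 and KRT17 4.87. The lists whose effects differed were the cell cycle (median difference -2.99), the unfolded protein and amino acid response (0.69), HIF targets (0.32) and basal epithelium (1.78). With an estimated correlation the cell cycle call held (camera, adjusted p = 4.81e-05) and the other calls were lost (adjusted p = 0.318 for the unfolded protein and amino acid response, 0.318 for HIF targets and 0.259 for basal epithelium).

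All 31 cell cycle genes fell in LNCaP. The tables argue against LNCaP CITED2 replicate 2 alone, and against GC content and length, as sources. Without that library 31 fell, and 31 fell with GC content and length trends removed (median -2.93). With library totals only, the list lay -2.91 from the median of all genes. A scaling factor moves all genes of a library alike, so it can hardly make or remove that gap, whichever scaling is used. The -2.91 is therefore no separate test of scaling. Fewer cells in cycle in the LNCaP CITED2 libraries may lie behind the fall. The members grouped as mitotic had a median of -3.69 and those grouped as S phase of -1.16. Both passed a limit that was set after the fall was seen. These medians therefore cannot tell fewer cells in cycle from another source of the fall. Growth was not measured in these data, and whether CITED2 or another difference between the groups led to the fall was not tested.

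LNCaP CITED2 replicate 2 stood apart from its sister libraries. Its deviation from them followed GC content (Spearman rho across genes 0.54, against at most 0.26 in the other libraries), so a GC-related step of library making may contribute. With GC and length trends removed the SD of its deviation was still 0.69, against at most 0.45 elsewhere, so those trends were not the whole source. Its total of 17.7 M counts was above the lowest LNCaP total of 14.9 M, which argues against a low total. It had 13194 genes with at least 10 counts, against 13816 to 14244 in the other LNCaP libraries. The total therefore does not settle the depth left for less abundant genes. No biological explanation was tested.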

How the results depend on the processing

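Library quality weights and the GC and length offset were chosen after the data were seen, and the other alternatives before the data were examined. CITED2 kept its rise in every alternative run, in 22Rv1 (log2 fold change 3.51 to 3.69) and in LNCaP (2.23 to 2.56). Of the values of named genes, 2937 kept their side of the threshold, 216 passed only in the alternative, 190 no longer passed and 0 reversed. Of the list results, 689 kept their side, 30 passed only in the alternative, 14 no longer passed and 1 reversed. A reversal was counted only where the main or the alternative value passed. A change of sign between values that both missed the threshold was counted as kept. Where no reason is given below, the cause was not tested.

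The count in 22Rv1 (3 with all libraries) was 27 with the DESeq2 Wald test, 9 with no filter, 487 with the line alone, 299 with quality weights, 12 with the GC and length offset and 566 with that offset and the line alone. Leaving out each library gave 2 to 737, the highest without LNCaP CITED2 replicate 2. The count in LNCaP (1164) was 566 at an adjusted p under 0.01, 537 with a fold of at least 2, 1919 with DESeq2, 606 with the line alone, 4816 with quality weights and 2445 with the offset. Leaving out each library gave 608 (LNCaP control replicate 3) to 4094 (LNCaP CITED2 replicate 2). The weight of LNCaP CITED2 replicate 2 was 0.051, and those of the other libraries 1.021 to 2.518. With library totals only, 24.4% of the LNCaP calls were higher (332 against 1029) instead of 39.7%, and the median of all genes moved from 0.001 to -0.148.

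The count that differed between the lines (419) was 247 at an adjusted p under 0.01, 764 with DESeq2, 2493 with quality weights and 901 with the offset, and 232 to 2835 when each library was left out. Genes called alike in both lines (1) were 2 with library totals only, 2 with DESeq2, 17 with each line alone, 73 with quality weights and 2 with the offset, and 1 to 164 when each library was left out. Lists called in 22Rv1 (2) were 5 with the offset, 4 with the offset and the line alone, 0 with an estimated correlation and 0 with fry, and 1 (without 22Rv1 control replicate 2) to 7 (without LNCaP CITED2 replicate 2). Lists called in LNCaP (3) were 1 with an estimated correlation and 7 with fry, which asks another question, and 2 to 5, the highest without LNCaP CITED2 replicate 3. Oxidative phosphorylation genes in LNCaP reversed without LNCaP CITED2 replicate 2, to a call for lower values (adjusted p = 0.00421, and 0.434 with an estimated correlation). Over the libraries left out the adjusted p ran from 0.00421 to 0.671.

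With the replicate number as a replicate block, 2 genes were called in 22Rv1, 694 in LNCaP and 268 in the difference. Libraries with the same number did not deviate together (r = -0.07 in 22Rv1, and 0.06, 0.00 and -0.05 in LNCaP), and not every library correlated best with its own number. These values gave no sign that the numbers pair the libraries, but they cannot exclude it. Deviations were taken from the group mean, so 22Rv1 gives only a single such comparison. In LNCaP the mean of the CITED2 group includes replicate 2, which stood apart.

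There are 10 splits of the 6 LNCaP libraries into 3 and 3, too few for a share under 0.05. The real split called 1164 genes, the highest other 0, and 1 split reached the real count. Every other split mixes control and CITED2 libraries on each side, which turns the real effect into spread within a side. The 0 is therefore no measure of what chance would call. For lists the real split called 3 and the highest other 5, and 8 splits reached 3.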

Other observations

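The single genes named here were chosen after their values were seen, while the tests of neighbouring genes were written before theirs. In LNCaP the androgen-glucuronidating enzyme genes UGT2B17 and UGT2B15 fell with KLK3, from 64.1 ± 2.84 to 2.32 ± 0.583 CPM (log2 fold change -4.79, adjusted p = 1.92e-06) and from 26.3 ± 0.989 to 1.11 ± 0.361 CPM (-4.58, adjusted p = 6.89e-07, edgeR). They can share reads, so the split between them is uncertain. KLK4 rose by 0.46 (adjusted p = 0.024) and IGF1R by 1.23 (adjusted p = 0.000101). The cell cycle regulators FOXM1, MYBL2 and E2F1 had log2 fold changes of -4.13, -3.88 and -2.27. CDKN1A was not called with all libraries (adjusted p = 1) and fell by 0.29 without LNCaP CITED2 replicate 2 (adjusted p = 0.000992). PCK2 and SLC1A4, genes of amino acid metabolism, rose by 1.27 and 1.53.

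Without LNCaP CITED2 replicate 2, 56 genes rose and 108 fell in both lines. Another 83 rose in 22Rv1 and fell in LNCaP, and 61 did the opposite. Across the tested genes other than CITED2 the fold changes again showed no correlation (Pearson r = 0.01). The genes below were picked from those called alike. Their log2 fold changes in 22Rv1 and LNCaP were -1.82 and -0.84 for HMOX1, -1.36 and -0.66 for COL18A1, -1.72 and -0.54 for COL6A2, -0.48 and -0.58 for COL6A1, -1.10 and -0.50 for JAG1, and -0.64 and -0.57 for TIMP2. The genes HRK (1.18 and 2.29), BEX1 (0.74 and 1.76) and ATF3 (0.52 and 0.60) rose in both. JAG1 was not called in the fit of the 22Rv1 libraries alone (edgeR, adjusted p = 0.186). With all libraries the effect on COL6A2 differed between the lines (1.38, edgeR, adjusted p = 0.0317).

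Neighbouring genes rose together in LNCaP in 24 next-neighbour pairs, against a median of 13 and a highest of 30 in 10000 random placements. That count was above the limit set beforehand for chance position but did not exceed every placement. Chance position was therefore neither accepted nor excluded. Without overlapping genes and gene family copies 15 pairs were left (median 10, highest 23), so shared reads may account for part of the excess. These 15 pairs lay on chromosomes 1, 2, 5, 8, 16, 17, 19, 20 and 22, so no single gained stretch of chromosome covers them. The other genes within 1 Mb of the pairs had a median log2 fold change of 0.1 (314 genes, quartiles -0.15 and 0.33). That value leaves gains at separate pairs open. Pairs that both fell numbered 69, against a median of 30 and a highest of 52. The falling pairs were not recounted without overlapping genes and gene family copies, so the part of shared reads in that excess was not tested.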
